A study of Homo sapiens with 26 samples.

How the data were processed

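RNA was measured by stranded, paired-end mRNA sequencing in OCI-Ly7 and SU-DHL-4 (SUDHL4), 2 established human lymphoma lines of the germinal centre B cell type of diffuse large B cell lymphoma. The lines carried a catalytically dead Cas9 fused to a KRAB repressor domain and guide RNAs against POU2F2, POU2AF1 or no target, so that transcription at the targeted promoter was repressed. The lines were grown in different media, OCI-Ly7 in IMDM and SUDHL4 in RPMI, each with serum. The labels also give a batch for each library, a series mark within batch 2 and, for 3 files, 48 h.

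According to the submitters' notes, the authors trimmed reads with fastp (version not given in the sources used here) and quantified them with Salmon 1.5.1 against GRCh38.p13. The release of the transcript annotation, the bias options and the library type are not given in the sources used here. Each of the 26 deposited files lists 227912 transcripts with their estimated counts of reads, their length, their effective length and their abundance as TPM. The deposited estimated counts were used, and the deposited TPM values were not. Of the transcripts, 205964 were matched by identifier, without the version number, to genes of GENCODE release 29, and the 21948 others were left out. The matched transcripts held 98.4% to 98.9% of the estimated reads of each file and belonged to 58592 genes. Estimated counts were summed per gene and rounded. Gene symbols were taken from a current gene table where it had the identifier, for 58201 genes.

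The files held 24959865 to 53155548 estimated reads each. Mitochondrially encoded genes took 7.04% to 25.8% of the reads and the 10 most abundant genes 6.83% to 24.7%. Intervals given for a share of reads are 95% Wilson intervals and cover counting error only.

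Files of 1 group were checked for repeats of the same library by comparing their difference with the sampling noise of their counts. The OCI-Ly7 control file numbered 3 equalled the sum of files 1 and 2, within 2 reads for 93.9% of 26833 genes with reads. OCI-Ly7 control files 1 and 2, SUDHL4 control files 1 and 2 and SUDHL4 POU2AF1 knockdown files 1 and 2 differed by about the sampling noise, with ratios of 1.126 to 1.132 over these 3 pairs, against 2.53 to 101 for 56 other pairs within groups. Pairs with a ratio below 1.5 were merged, and the file that repeated a sum was not added again, which left 22 libraries. The merging threshold was set after the repeats were seen. OCI-Ly7 then had 4 control libraries (1 of batch 1 and 3 of batch 2), 6 POU2AF1 knockdown libraries (4 of batch 1 and 2 of batch 2) and 8 POU2F2 knockdown libraries, all of batch 2 per the labels. SUDHL4 had 1 control library, 1 POU2AF1 knockdown library and 2 POU2F2 knockdown libraries, all of batch 1. The merging was tested on simulated data.

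Each line was fitted on its own with edgeR 4.0.16 (TMM normalisation, filterByExpr with a minimum count of 10, robust quasi-likelihood fit and test), with batch as a term in OCI-Ly7. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested were called. The biological coefficient of variation was 0.297 in OCI-Ly7 and 0.0779 in SUDHL4. In SUDHL4 the only 2 replicate libraries leave 1 residual degree of freedom, and the lone control and POU2AF1 knockdown libraries are assumed to vary like these. For that reason all 22 libraries were also fitted together, and genes and lists named for SUDHL4 that lost the call there are given as such. In this fit the spread comes mainly from OCI-Ly7, with a coefficient of variation of 0.298. Differences between the lines were tested in the same fit as interaction contrasts. Fold changes are fitted log2 values with their standard error, and group levels are TMM-normalised CPM with the standard deviation over libraries.

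Within batch 2, libraries that share a series mark (s0, s1, s2 or s3) resembled each other, so a fit with the series as a block in place of the 2 batches was added. It was chosen after seeing the data, compares libraries within a series, and is called the series block. POU2F2 knockdown replicates 1 and 3 each stand alone in their block, so they add nothing to the fitted differences between groups there. Its coefficient of variation was 0.146.

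Of 27 gene lists, those with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation preset at 0.01), and again with an estimated correlation and with fry. The lists covered the POU2F and POU2AF family, B cell receptor signalling, germinal centre B cell identity, plasma cells, naive and memory B cells, the CD40 and NF-kB response, immediate early genes, MHC class II, immunoglobulin constant genes with the J chain, S phase, G2 and M phase, MYC targets with ribosome biogenesis, the type I interferon response, the p53 response, apoptosis regulators, the ATF4 and amino acid response, endoplasmic reticulum chaperones, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytoplasmic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones and chemokine and adhesion genes. The remaining lists held markers of T and NK cells, of myeloid cells and of epithelial and fibroblast cells. The POU2F and POU2AF family was described gene by gene.

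The comparisons, tests, thresholds, gene lists, first set of alternatives and the rule for named genes were fixed before the data were examined. The merging of repeated files, which sets the libraries in each fit, the fit of all libraries for lists and overlaps and the test of the germinal centre list without both targeted genes came later. The rule takes both targets in every comparison; the 10 largest rises and falls among called protein-coding genes with a mean of at least 5 CPM and every knockdown library on that side of the controls of its batch; the 8 largest shared rises and falls over both lines; 5 genes each way between the knockdowns; the 5 smallest adjusted p for a difference between lines; and up to 4 members per list. Genes named from the series block follow the same rule in that fit. Overlaps of called genes were tested with Fisher's exact test, and where both comparisons share controls they were set against 20 simulated draws of unchanged groups.

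In simulated data with 200 changed genes per comparison, the OCI-Ly7 fit recovered 42% to 44% of 2-fold changes and 79% to 83% of 4-fold changes, with 3 to 9 unchanged genes called. The SUDHL4 fit recovered 57% of 2-fold changes and 76% to 81% of 4-fold changes, with 39 to 43 unchanged genes called, well above the nominal rate, so its calls include more false ones than the threshold allows. The tests of line differences recovered 0% to 2% of 2-fold and 22% to 38% of 4-fold changes. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, effective lengths as an offset, a glmTreat test against 2-fold, other blocks and batch terms, single batches, the 2 compared groups alone, all libraries in 1 fit, files kept separate, and leaving out each library or the 48 h libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Under every scaling tried the median log2 fold change over all genes tested lay between -0.04 and 0.02.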

Results

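The transcriptomes of 2 germinal centre B cell lymphoma lines, OCI-Ly7 and SUDHL4, were compared after CRISPR interference against POU2F2 or POU2AF1. POU2F2 encodes OCT2, an octamer-binding transcription factor of B cells, and POU2AF1 encodes OCA-B, the coactivator that OCT proteins recruit. The series sets each knockdown against the control guides of its line, to find the genes whose expression moves with the loss of either factor. After repeated files were merged there were 22 libraries. OCI-Ly7 had 4 control, 6 POU2AF1 knockdown and 8 POU2F2 knockdown libraries, and SUDHL4 had 1, 1 and 2. The files held 24959865 to 53155548 estimated reads each. The labels do not say that replicates come from separate cultures, so the p-values measure only the spread between these samples. The single SUDHL4 control and POU2AF1 knockdown libraries have no replicates, so they carry no SD, and the standard errors and p-values of their comparisons borrow the spread of other libraries.

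The targeted genes were measured first. POU2AF1 (chromosome 11, 111352252 to 111455630 on GRCh38, minus strand, ENSG00000110777) was at 448, 462, 453 and 479 CPM in the OCI-Ly7 control libraries. It fell to 27.8, 42.9, 32.3 and 30.4 CPM in the batch 1 POU2AF1 knockdown libraries and to 89.5 and 82.7 CPM in those of batch 2. The group means were 461 ± 14 CPM (SD, n = 4) and 50.9 ± 28 CPM (SD, n = 6), and the fitted log2 change was -3.0 ± 0.19 (standard error; edgeR adjusted p = 2e-07). In SUDHL4 it was at 405 CPM in the control and 74.1 CPM in the POU2AF1 knockdown, a log2 change of -2.45 ± 0.13 (adjusted p = 1e-16, and 0.0039 in the fit of all libraries). POU2F2 (ENSG00000028277, chromosome 19, 42086110 to 42196585 on GRCh38, minus strand) was at 409.5 CPM in the batch 1 OCI-Ly7 control and at 242, 251 and 211 CPM in the batch 2 controls. The POU2F2 knockdown libraries, replicates 1 to 8, held 59.2, 89.4, 150, 56.5, 62.8, 75.4, 90.4 and 65.4 CPM, all below the batch 2 controls. Their mean was 81.1 ± 31 CPM (SD, n = 8) against 278 ± 89 CPM (SD, n = 4). The fitted log2 value of -1.57 ± 0.24 narrowly missed the threshold (adjusted p = 0.056), and within series it was -1.73 (adjusted p = 0.0022). In SUDHL4 POU2F2 fell from 303 CPM to 40.6 and 52.1 CPM, a log2 change of -2.71 ± 0.13 (adjusted p = 1.2e-07, and 0.018 in the fit of all libraries, where the call was lost without POU2F2 knockdown replicate 1, at 0.32, and without replicate 2, at 0.083).

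Each factor was also followed after loss of the other. In OCI-Ly7 the log2 value of POU2AF1 after POU2F2 knockdown was -0.27 ± 0.19 and that of POU2F2 after POU2AF1 knockdown was -0.18 ± 0.27, and neither was called. In SUDHL4 POU2F2 was at 461 CPM after POU2AF1 knockdown, a rise of 0.61 on the log2 scale in the fit of that line (adjusted p = 0.0082) but not in the fit of all libraries (adjusted p = 0.78). POU2F1, which encodes the ubiquitous OCT1, fell in the same library from 97.7 to 51.3 CPM (log2 change -0.93, adjusted p = 1.3e-08, and 0.12 in the fit of all libraries).

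**Figure D1:**
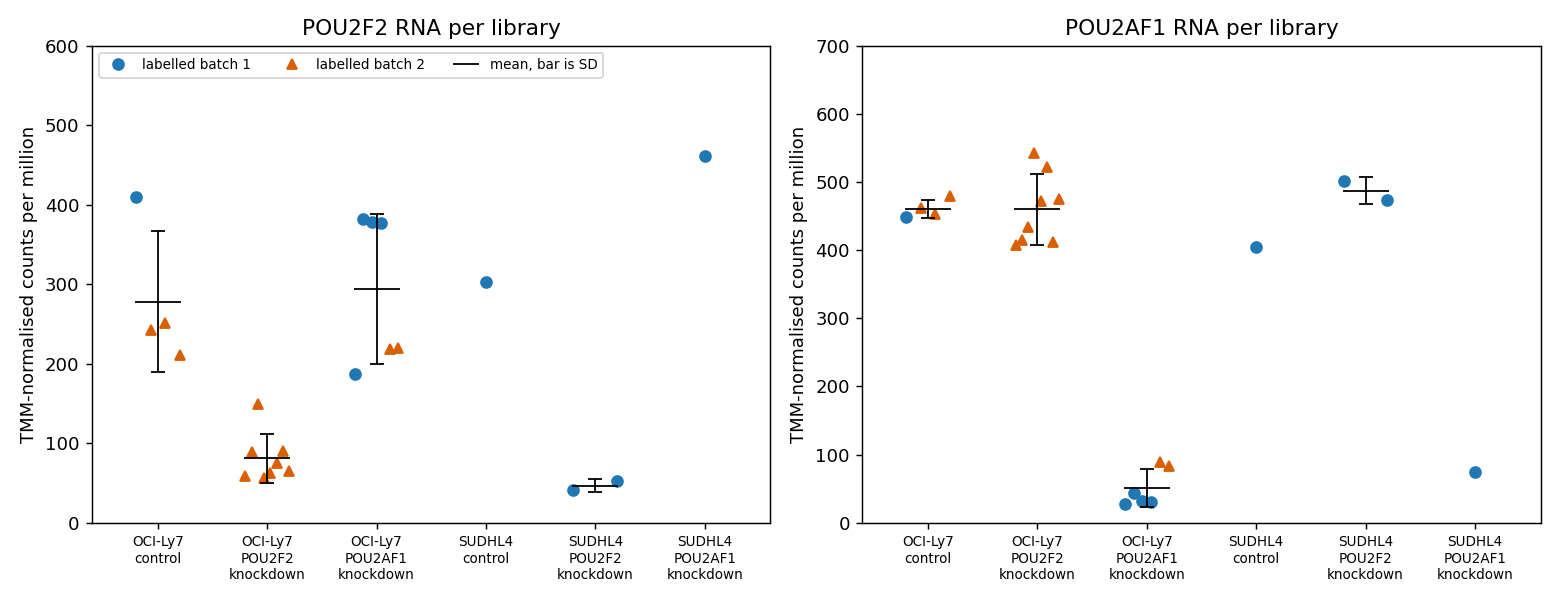
Normalised expression of POU2F2 and POU2AF1 (TMM-normalised CPM, vertical axis) in each of the 22 libraries, by cell line and group, with marker shapes for the batch and bars for the mean and SD. Each target is lowest in the group that was targeted, and the POU2F2 knockdown library at 150 CPM is replicate 3.

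OCI-Ly7 libraries differed by more than the knockdown. The first dimension of a multidimensional scaling of the 18 libraries held 28.1% of the variance and the second 17.4%. The batch 1 libraries and POU2F2 knockdown replicate 3 lay on one side, and the batch 2 libraries lay by their series mark. Within series every OCI-Ly7 gene named below from the fit with batch kept its call, and lists that crossed the threshold are given with their value within series. Both fits use the same single batch 1 control library.

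**Figure D2:**
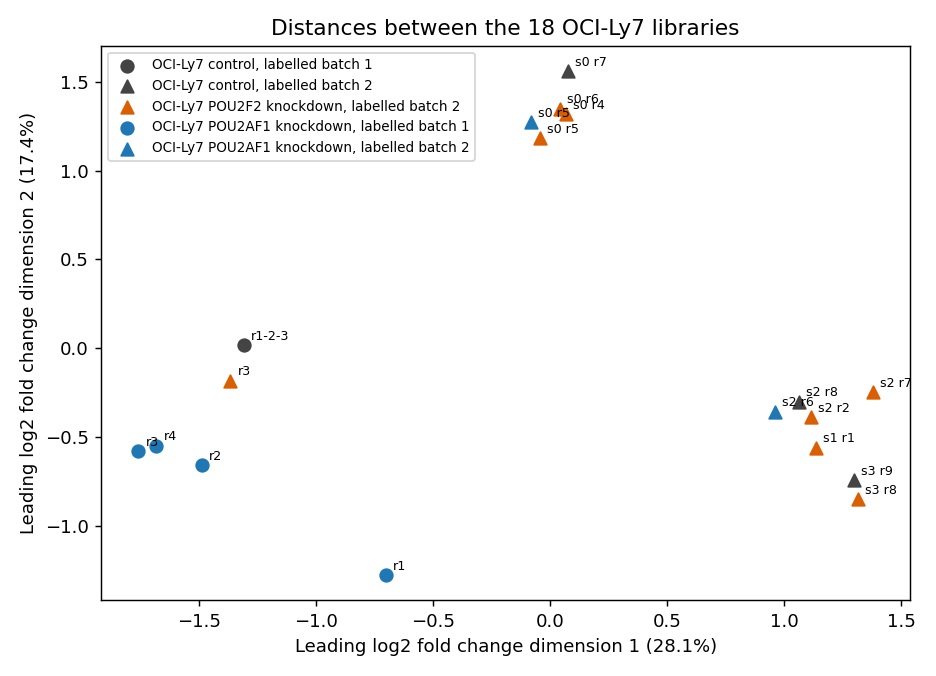
Multidimensional scaling of the 18 OCI-Ly7 libraries from leading log2 fold changes (dimension 1 across, 28.1% of the variance, and dimension 2 up, 17.4%), coloured by group, with marker shapes for the batch and series marks as text. Libraries of series s0 lie together whichever guide they carried, and POU2F2 knockdown replicate 3 lies with batch 1.

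In OCI-Ly7, loss of POU2AF1 was accompanied by lower expression of genes of the germinal centre programme. BCL6 (ENSG00000113916, chromosome 3, 187721377 to 187745727 on GRCh38, minus strand), the repressor that maintains germinal centre B cells, fell from 345 ± 52 CPM (SD, n = 4) to 117 ± 29 CPM (SD, n = 6), a log2 change of -1.44 ± 0.18 (adjusted p = 0.00041). IRF8, a transcription factor of germinal centre B cells, fell from 180 ± 22 to 76.9 ± 12 CPM (log2 change -1.22 ± 0.14, adjusted p = 0.00015). RGS13, a regulator of G protein signalling in these cells, fell from 122 to 49.3 CPM, and MYBL1, a MYB family transcription factor, fell by 1.40 on the log2 scale. NUGGC, a nuclear GTPase of germinal centre B cells, fell from 150 ± 38 to 50.7 ± 20 CPM (log2 change -1.22 ± 0.15). Each of these genes was lower in 6 of 6 knockdown libraries than the controls of its batch, which in batch 1 are a single library. For BCL6 and NUGGC, named as shared falls, the rule for named genes required this.

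By the rule for named genes, the largest falls after POU2AF1 knockdown in OCI-Ly7 outside the target itself were in genes of several kinds. GNB3 (ENSG00000111664, chromosome 12, 6839954 to 6847393, plus strand), a G protein beta subunit, fell from 35.1 ± 3.3 to 4.43 ± 2.5 CPM (log2 change -2.86 ± 0.27, adjusted p = 2.1e-05). LOXL2, a lysyl oxidase, fell from 36.6 to 8.06 CPM (log2 change -2.0 ± 0.17). KCNN3, a calcium-activated potassium channel, fell from 76.8 to 14.1 CPM, and MYH11, a smooth muscle myosin heavy chain, fell from 81.9 to 19.7 CPM. The gluconeogenic enzyme FBP1 (-1.95), the Wnt ligand WNT5A (-1.79), PDZRN4 (-2.14), MACROD2 (-1.60) and NLRP4 (-1.53) also fell on the log2 scale. By the same rule the largest rises were in CHD1, a chromatin remodeller, from 7.58 ± 0.65 to 26 ± 5.6 CPM (log2 change 1.65 ± 0.25, adjusted p = 0.0021), SP140, a nuclear body protein (1.58), and KLHL14 (1.56). ETV6, an ETS family repressor, rose from 43.2 to 99.1 CPM, and AAK1 (1.17), the fatty acid elongase ELOVL6 (1.10), CMTM7 (0.94), RUFY3 (0.91), OGFRL1 (0.91) and STK17A (0.89) rose as well. All of these held in 6 of 6 libraries, which the rule for named genes required.

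Of 16002 genes tested, 142 were called after POU2AF1 knockdown in OCI-Ly7, 45 higher and 97 lower. The fitted change was at least 2-fold in 76 of them. Fewer passed the glmTreat test against 2-fold, whose counts are given further below. The series block called 893, with 399 higher and 494 lower. Batch 1 alone called 24 and batch 2 alone 7. Leaving out the single batch 1 control library left 8 calls, so most of the genes named above were not called without it. Leaving out POU2AF1 knockdown replicate 5 left 85. Replicate 1 of this group drew 25.8% of its reads (95% Wilson interval 25.81% to 25.83%) from mitochondrially encoded genes, against 7.04% to 9.74% in the other 5 libraries, and lacking it the series block called 1693 genes. Genes that the series block alone brought in included ZEB2, a transcriptional repressor (log2 change 2.11), the cell cycle inhibitor CDKN1A (1.67), CEMIP2 (2.20), the lipid antigen presenter CD1C (-2.21) and the complement receptor CR2 (-1.89).

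Among the gene lists in the POU2AF1 knockdown of OCI-Ly7, germinal centre B cell identity had the smallest camera p with batch as a term. Of 31 tested members 7 fell and none rose, and 10 fell when p was adjusted over the list alone. POU2AF1 itself is among the 7. The list's median log2 value was -0.18 (camera adjusted p = 1.9e-11, and adjusted p = 0.0051 with an estimated correlation). Without both targeted genes the adjusted p was 6.9e-09, and 0.0086 with an estimated correlation. Within series the adjusted p with an estimated correlation was 0.14. The naive and memory B cell list rose as a set, with a median of 0.57 over 17 members (adjusted p = 0.00074, and adjusted p = 0.011 with an estimated correlation). With batch as a term 1 member rose, S1PR1, the receptor for egress from lymphoid tissue (log2 change 3.17 ± 0.72, adjusted p = 0.042). It started from a low level, at 0.34 CPM in the controls and 4.6 CPM in the knockdown. The interleukin 4 receptor chain IL4R was the 1 that fell (-1.30). Adjusted over the list alone 4 were higher and 2 lower. Within series 8 members were called higher and 2 lower, and the adjusted p of the list with an estimated correlation was 0.14. Markers of T and NK cells, of which 10 of 24 were expressed enough to test in OCI-Ly7, had a median of 0.47 (adjusted p = 0.00045, and adjusted p = 0.021 with an estimated correlation), and TRBC2 rose by 0.75 on the log2 scale. The adjusted p of these markers as a set with an estimated correlation was 0.18 within series. Of these markers 4 were higher adjusted over the list alone.

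With batch as a term the B cell antigen receptor and its partners gave fewer calls than the germinal centre list, a difference that was not tested. Within series 1 germinal centre member was called higher and 11 lower. The immunoglobulin heavy chain gene IGHM fell from 5569 to 2946 CPM (log2 change -0.90, adjusted p = 0.0029) and the surrogate light chain partner VPREB3 fell by 1.05 on the log2 scale. Of 13 immunoglobulin list members these 2 fell, and adjusted over the list alone 1 was higher and 4 were lower. Within series 2 of them were called higher and 5 lower. The list's median was -0.38 and its mean 0.03, and camera placed it lower (adjusted p = 0.022, but adjusted p = 0.38 with an estimated correlation and 0.086 within series). CD22, an inhibitory coreceptor, fell from 740 to 406 CPM (adjusted p = 0.0026). With batch as a term it was the only called member of the 29 of B cell receptor signalling (list adjusted p = 0.14). Adjusted over that list alone 1 was higher and 5 were lower, and within series 2 members were called higher and 7 lower. MHC class II had a median of -0.28 (adjusted p = 0.033, but adjusted p = 0.85 with an estimated correlation). No member was called, and adjusted over the list alone 1 was higher and 1 lower. The alpha chain HLA-DRA was at -0.76 (adjusted p = 0.097, and 0.00047 within series).

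The ATF4 and amino acid list (0.11), the cytoplasmic ribosomal proteins (0.11) and G2 and M phase (-0.06) were also called as sets in the OCI-Ly7 POU2AF1 knockdown, by small medians without a called member. Their adjusted p with an estimated correlation was 0.85, 0.93 and 0.85. In the list of chemokine and adhesion genes S1PR1 and the integrin chain ITGA4 (0.56) rose and RGS13 fell, with 3 higher and 4 lower adjusted over the list alone (list adjusted p = 0.79). SYVN1, a ubiquitin ligase of endoplasmic reticulum quality control, fell by 0.70 on the log2 scale and was the only call among 24 chaperone genes (list adjusted p = 0.22). No member was called in the lists of plasma cells (list adjusted p = 0.94), the CD40 and NF-kB response (0.94), immediate early genes (0.056), S phase (0.17), MYC targets (0.26), interferon response (0.14), p53 response (0.74), apoptosis regulators (0.74), cholesterol synthesis (0.92), glycolysis (0.61), oxidative phosphorylation (0.94), mitochondrially encoded genes (0.55), histones (0.73) or myeloid markers (0.28). Within series chaperones (median -0.26, 7 members lower, adjusted p = 0.00055), S phase (-0.09, 4 lower, adjusted p = 0.00055), immediate early genes (0.56, adjusted p = 0.0071) and oxidative phosphorylation (-0.08, adjusted p = 0.012) were called as sets, but with an estimated correlation their adjusted p was 0.63 or above.

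After POU2F2 knockdown in OCI-Ly7 no gene passed the threshold with batch as a term, so the following are measured values. BCL6 was at 231 ± 32 CPM (SD, n = 8) against 345 ± 52 CPM (SD, n = 4) in the controls, and lower in 8 of 8 libraries (log2 value -0.66 ± 0.16, not called). MYBL1 was at 47.6 ± 5.3 against 83.2 ± 26 CPM and NUGGC at 110 ± 19 against 150 ± 38 CPM. Within series both fell, MYBL1 by a log2 change of -0.87 (adjusted p = 0.0078) and NUGGC by -0.56 (adjusted p = 0.038), as did the phosphatase PTPN18 (-0.50, adjusted p = 0.0078). POU2F2 knockdown replicates 1 and 3 stand alone in their blocks in that fit and add nothing to its fitted values. Within series the interleukin 7 receptor IL7R (0.54, adjusted p = 0.0092), the RAS-binding protein RASSF5 (0.56, adjusted p = 0.034) and the phosphatase PTPN1 (0.31, adjusted p = 0.046) rose. With POU2F2 knockdown replicate 3 placed in batch 1 only MYBL1 (adjusted p = 0.0089) and POU2F2 itself were called within series, and NUGGC (0.061), PTPN18 (0.069), IL7R (0.087), RASSF5 (0.055) and PTPN1 (0.069) were not. Without POU2AF1 knockdown replicate 1 all 6 kept the call within series. The edgeR test with batch called 0 of 16002 genes, with 283 at an unadjusted p below 0.05. DESeq2 called 5, with 2 higher and 3 lower, and the series block 13, with 8 higher and 5 lower. The series block called 2 with POU2F2 knockdown replicate 3 in batch 1, and 135 without POU2AF1 knockdown replicate 1.

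As sets, 12 of 25 lists were called after POU2F2 knockdown in OCI-Ly7, 9 higher and 3 lower, but with an estimated correlation only naive and memory B cell genes remained. Their median was 0.49 over 17 members (adjusted p = 9.6e-08, and adjusted p = 0.00045 with an estimated correlation; within series 0.057). No member passed over all genes, and 5 were higher adjusted over the list alone. Values were 0.49 for the antiproliferative gene BTG1, 0.66 for the receptor TNFRSF13B, 1.38 for the transcription factor KLF2 and 1.80 for S1PR1. Within series they were 0.36, 0.77, 0.855 and 1.95. The CPM means, which take no account of batch, were 33.4 against 30.4 in the controls for BTG1 and 13.1 against 7.81 for TNFRSF13B. They were 5.36 ± 4.0 against 4.19 ± 4.0 for KLF2 (SD) and only 0.99 against 0.34 for S1PR1. MHC class II had a median of 0.16 (adjusted p = 1.9e-05, but adjusted p = 0.25 with an estimated correlation; 1 higher adjusted over the list alone). The germinal centre list had a median of -0.02, a mean of -0.12 and was placed lower (adjusted p = 0.0014, but adjusted p = 0.17 with an estimated correlation), with 3 lower adjusted over the list alone. POU2F2 itself is a member, and without both targeted genes the mean was -0.06 and the adjusted p 0.032, or 0.29 with an estimated correlation. Glycolysis and hypoxia genes had a median of -0.25 (adjusted p = 6.6e-07, but adjusted p = 0.31 with an estimated correlation), and within series the median was 0.01.

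The other called lists of this comparison were immediate early genes (median 0.63), histones (0.46), T and NK markers (0.23), interferon response (0.15), CD40 and NF-kB response (0.16), B cell receptor signalling (0.08) and plasma cells (0.06), all higher, and S phase (-0.08), lower. With an estimated correlation their adjusted p was 0.29, 0.40, 0.17, 0.32, 0.41, 0.24, 0.17 and 0.54, in that order. Not called were immunoglobulin genes (list adjusted p = 0.81), G2 and M phase (0.81), MYC targets (0.062), p53 response (0.11), apoptosis regulators (0.096), ATF4 and amino acid response (0.11), chaperones (0.13), cholesterol synthesis (0.45), oxidative phosphorylation (0.18), ribosomal proteins (0.074), mitochondrially encoded genes (0.46), chemokine and adhesion genes (0.13) and myeloid markers (0.15). Within series immediate early genes (median 0.18, adjusted p = 0.091), histones (0.22, adjusted p = 0.12), CD40 and NF-kB (0.04, adjusted p = 0.28), B cell receptor signalling (0.05, adjusted p = 0.073) and plasma cells (0.02, adjusted p = 0.33) were not called. Called there instead were MYC targets (-0.23, adjusted p = 3.3e-14), ATF4 (0.09, adjusted p = 0.0019), oxidative phosphorylation (-0.08, adjusted p = 0.00062) and ribosomal proteins (0.05, adjusted p = 0.033), with an adjusted p of 0.46 or above for an estimated correlation.

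In SUDHL4, 1 POU2AF1 knockdown library had higher expression of interferon, antigen presentation and B cell signalling genes and lower expression of cell cycle genes than 1 control library. In this line's own fit no list kept its call with an estimated correlation, and the values in the fit of all libraries are given below. MPEG1, which encodes a pore-forming protein of phagocytes, was at 106 CPM against 1.62 CPM in the control, the Fc receptor-like gene FCRL5 at 44.2 against 1.37 CPM, and the cytokine TNF at 64.7 against 2.94 CPM. The phosphatase PTPN6 (SHP-1) rose from 4.43 to 84.9 CPM, a log2 change of 4.26, and was also called in the fit of all libraries (adjusted p = 0.0001). C16orf74 (6.80), TMPRSS15 (6.63), the kinase LRRK2 (4.39), UBA7 (4.13), FCGBP (4.11) and the immediate early gene EGR1 (3.96) rose as well. BCL6 fell from 645 to 223 CPM (log2 change -1.53, adjusted p = 0.039 in the fit of all libraries), and SERPINA9, a germinal centre marker, fell from 86.1 to 19 CPM. Further falls were in RSC1A1 (-2.62), CCDC144A (-2.53), GNB3 (-2.31), LOXL2 (-2.27), ARHGEF28 (-2.24), MYH11 (-2.22), the potassium channel KCNC4 (-2.12) and the glycolysis regulator PFKFB4 (-2.09). MPEG1, UBA7, EGR1, SERPINA9, RSC1A1, CCDC144A, ARHGEF28, MYH11 and PFKFB4 lost the call in the fit of all libraries (adjusted p from 0.065 to 0.87), and the others named here kept it.

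The fit of SUDHL4 alone called 6245 of 16968 genes, 3057 higher and 3188 lower, 1911 of them with a fitted change of at least 2-fold. Here too fewer passed the glmTreat test against 2-fold. The fit of all libraries called 315, with 210 higher and 105 lower. This comparison sets 1 library against 1, and the spread is borrowed from other groups. The POU2AF1 knockdown library drew 12.8% of its reads from mitochondrially encoded genes and the control 9.76%, and what part this plays was not tested.

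The cell cycle and interferon lists moved nearly as a whole in the SUDHL4 POU2AF1 knockdown. Of 52 tested G2 and M phase genes 51 fell, with a median of -0.78 (adjusted p = 5.7e-23), and the mitotic kinase CDK1 fell from 183 to 84.7 CPM. Of 43 S phase genes 41 fell, with a median of -0.73 (adjusted p = 2.4e-19), among them DTL (-1.18), a factor of replication-coupled degradation. Of 32 interferon response genes 29 rose and 1 fell, with a median of 1.96 (adjusted p = 8.5e-15), among them IFIT2 (4.79), SAMD9L (4.95), IFI6 (3.61) and the regulator IRF7 (2.44). All 14 MHC class II genes rose, with a median of 1.21 (adjusted p = 7.3e-12), among them HLA-DMB (2.09), HLA-DQB1 (2.09) and the transactivator CIITA (1.77). Adjusted over the list alone 51 G2 and M phase and 42 S phase genes were lower, 31 interferon genes were higher and 1 lower, and 14 MHC class II genes were higher. In this line's own fit no list kept its call with an estimated correlation (adjusted p of 0.59 or above). In the fit of all libraries these 4 did, with adjusted p of 0.0027, 0.028, 0.00095 and 0.041 in that order. Of the genes named, IRF7 (0.075) and CIITA (0.079) lost the call there.

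B cell receptor signalling and naive and memory genes rose as well in the SUDHL4 POU2AF1 knockdown. Of 29 B cell receptor signalling genes 21 rose and 2 fell (median 0.69, adjusted p = 4e-08), with CD72 at 2.56. Of 21 naive and memory genes 15 rose (median 2.35, adjusted p = 9.3e-09), with TXNIP at 2.60 and BTG1 at 1.56. In the fit of all libraries these 2 lists held with an estimated correlation, at adjusted p of 0.0027 and 0.00022. Of 29 chemokine and adhesion genes 17 rose and 1 fell (median 0.47, adjusted p = 0.0001), and this list held in the fit of all libraries at 0.014. Of 28 CD40 and NF-kB genes 19 rose and 1 fell (median 0.90, adjusted p = 6e-07), with the lymphotoxins LTB at 3.24 and LTA at 2.64 and SLAMF1 at 2.76. Of 40 ribosomal protein genes 37 rose (median 0.59, adjusted p = 1e-11). MYC fell from 487 to 224 CPM, and 23 of 40 MYC target genes, MYC among them, fell (median -0.36, adjusted p = 9.3e-07). Of 26 ATF4 genes 16 fell and 4 rose (median -0.52, adjusted p = 0.0001), with the amino acid enzyme ASNS at -1.32 and the cystine transporter SLC7A11 at -1.61. Adjusted over the list alone the higher and lower members were 21 and 2 for B cell receptor signalling, 17 and 1 for naive and memory genes, 17 and 2 for chemokine and adhesion genes, 19 and 3 for CD40 and NF-kB, 39 and 0 for ribosomal proteins, 1 and 26 for MYC targets and 4 and 17 for ATF4. With an estimated correlation in the line's own fit the adjusted p of these lists was 0.59 or above. It was 0.14 for CD40 and NF-kB, 0.35 for ribosomal proteins, 0.72 for MYC targets and 0.14 for ATF4 in the fit of all libraries, where TXNIP (0.089), MYC (0.053) and ASNS (0.07) were not called.

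Glycolysis and hypoxia genes fell as a set in this comparison, with 15 lower and 1 higher of 27 (median -0.53, adjusted p = 0.0001), as did oxidative phosphorylation, with 14 lower and 2 higher of 35 (median -0.22, adjusted p = 0.0011). Of 17 immunoglobulin genes 7 rose and 1 fell (median 0.68, adjusted p = 0.0031), and of 26 apoptosis regulators 11 rose and 2 fell (median 0.08, adjusted p = 0.035). With an estimated correlation the adjusted p was 0.59, 0.75, 0.61 and 0.61 in that order. Only oxidative phosphorylation was called in the fit of all libraries (adjusted p = 0.033, but 0.72 with an estimated correlation). Lists not called as sets still held called members going both ways. Of 34 germinal centre genes 19 rose and 9 fell (list adjusted p = 0.064, and 0.036 without both targeted genes, but then 0.74 with an estimated correlation), of 21 plasma cell genes 5 rose and 7 fell (0.90), and of 21 p53 response genes 6 rose and 6 fell (0.88), with TP53INP1 at 2.23 and BTG2 at 1.52, neither called in the fit of all libraries. Immediate early genes had 9 higher and 3 lower of 19 (0.05), chaperones 6 and 3 of 24 (0.19), cholesterol synthesis 4 and 4 of 24, mitochondrially encoded genes 3 and 0 of 13 (0.05) and histones 2 and 0 of 18 (0.86). The higher and lower members adjusted over the list alone were 1 and 15 for glycolysis, 3 and 15 for oxidative phosphorylation, 8 and 1 for immunoglobulin genes, 11 and 2 for apoptosis regulators, 20 and 9 for germinal centre identity, 7 and 7 for plasma cells and 7 and 6 for the p53 response.

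Markers of other cell types also moved in the SUDHL4 POU2AF1 knockdown. Of 12 T and NK markers tested 6 rose and 1 fell, with TRAC at 2.93 and CD247 at -1.72 (list adjusted p = 0.12). Of 8 myeloid markers 3 rose, with CD68 at 3.01 (list adjusted p = 0.064, and 0.044 in the fit of all libraries, but 0.12 there with an estimated correlation). Of 6 epithelial and fibroblast markers 2 rose (list adjusted p = 0.12). TRAC (0.069), CD247 (0.27) and CD68 (0.4) lost the call in the fit of all libraries. In SUDHL4, 12 of the 24 listed T and NK markers, 8 of the 21 myeloid markers and 6 of the 17 epithelial and fibroblast markers were expressed enough to test.

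After POU2F2 knockdown in SUDHL4 TNF rose from 2.94 to 17.2 ± 2.4 CPM (SD, n = 2), a log2 change of 2.55 ± 0.16, and PTPN6 from 4.43 to 23.5 ± 2.6 CPM (log2 change 2.41 ± 0.14, adjusted p = 0.034 in the fit of all libraries). TMPRSS15 (4.04), C16orf74 (3.85), MS4A7 (2.46), SMIM14 (2.43), PLEKHO1 (2.42), GPR82 (2.41), the endotoxin receptor TLR4 (2.21) and SERINC2 (2.14) rose as well. The kinase PRKCB (2.01), which acts in B cell receptor signalling, and the tetraspanin CD53 (1.38) were called in both fits. By the rule for named genes the largest falls outside the target were smaller, with SLC10A3 at -1.13, KIAA0040 at -1.05, DLG2 at -1.02, EPN2 at -0.97, the purine enzyme ADA at -0.92, the kinase PIM1 at -0.91, CD247 at -0.88, and CLTCL1 and PAX9 at -0.83 each. BCL6 fell from 645 to 395 CPM (log2 change -0.71), and NUGGC fell by 0.76, PTPN18 by 0.43 and MYBL1 by 0.35 on the log2 scale. Of the rises named here TMPRSS15, PLEKHO1, PTPN6, PRKCB and CD53 kept the call in the fit of all libraries, and the rest did not (adjusted p of 0.11 or above), nor did any of the falls (0.9 or above). The fit of SUDHL4 alone called 1249 genes, 814 higher and 435 lower, and the fit of all libraries 18, with 10 higher and 8 lower. The 18 became 5 without POU2F2 knockdown replicate 1 and 14 without replicate 2. Of the rises that kept the call, PLEKHO1 held it with either library left out (adjusted p = 0.049 without replicate 1 and 0.027 without replicate 2) and PRKCB without replicate 2 (0.027) but not without replicate 1 (0.12). TMPRSS15 (0.13 and 0.059), PTPN6 (0.21 and 0.06) and CD53 (0.34 and 0.083) lost it with either one left out.

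MHC class II and interferon genes had the smallest camera p with the preset correlation after POU2F2 knockdown in SUDHL4. Of 14 MHC class II genes 11 rose (median 0.55, adjusted p = 4.3e-12), with HLA-DQB1 at 0.91, CIITA at 0.63 and HLA-DMB at 1.10. Of 32 interferon genes 15 rose and none fell (median 0.49, adjusted p = 1.9e-11), and 21 were higher adjusted over the list alone, with IFIT2 at 2.75 and SAMD9L at 2.61. B cell receptor signalling had 12 of 29 higher (median 0.28, adjusted p = 2.3e-09; 15 adjusted over the list alone), with CD72 at 0.90. Naive and memory genes had 8 of 21 higher (median 0.63, adjusted p = 4.3e-08; 11 adjusted over the list alone), with FCRL5 at 1.85, HHEX at 1.34 and TXNIP at 1.08. CD40 and NF-kB genes had 11 of 28 higher (median 0.36, adjusted p = 9.2e-10), with SLAMF1 at 1.92 and LTB at 1.14. The ATF4 list had 8 lower and 1 higher of 26 (median -0.23, adjusted p = 1.5e-07), with ASNS at -0.65. When adjusted over the list alone 12 MHC class II and 14 CD40 and NF-kB genes were higher, and 13 ATF4 genes were lower and 1 higher. With an estimated correlation every list of this comparison had an adjusted p of 0.57 or above in the line's own fit. In the fit of all libraries interferon genes (0.0075), B cell receptor signalling (0.0075) and naive and memory genes (0.0023) kept the call with an estimated correlation, and MHC class II did not (0.15), nor did CD40 and NF-kB or ATF4 (0.17 each). Of the genes named HLA-DMB alone was called there (adjusted p = 0.049, the others 0.37 or above), and not without POU2F2 knockdown replicate 1 (0.33) or replicate 2 (0.14).

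Further lists were called as sets after POU2F2 knockdown in SUDHL4. G2 and M phase had 5 lower of 52 (median -0.13, adjusted p = 3.5e-08) and S phase 3 lower of 43 (median -0.12, adjusted p = 1.2e-05). Cholesterol synthesis had 7 higher of 24 (median 0.24, adjusted p = 1.2e-05), chaperones 5 higher of 24 (0.15, adjusted p = 0.0037) and chemokine and adhesion genes 5 higher of 29 (0.23, adjusted p = 0.0019). Oxidative phosphorylation had 1 lower of 35 (-0.11, adjusted p = 2.9e-05), glycolysis 2 lower of 27 (-0.13, adjusted p = 0.027), ribosomal proteins none of 40 (0.11, adjusted p = 0.011) and mitochondrially encoded genes 1 higher of 13 (0.42, adjusted p = 0.0073). The share of reads from mitochondrially encoded genes was 14.04% in POU2F2 knockdown replicate 1 and 10.26% in replicate 2, against 9.76% in the control, so most of the difference in share lies in replicate 1, and the list was not tested without it. The germinal centre list had 10 higher and 5 lower of 34 (0.12, adjusted p = 0.023, and 0.0075 without both targeted genes), with the B cell antigen MS4A1 at 0.97 and the chemokine receptor CXCR5 at 0.54. T and NK markers had 4 higher and 1 lower (0.55, adjusted p = 0.044), with TRAC at 1.92, myeloid markers 1 higher (1.00, adjusted p = 0.044), with CD68 at 1.48, and epithelial and fibroblast markers none (1.63, adjusted p = 0.011). Adjusted over the list alone the higher and lower members were 0 and 5 for G2 and M phase, 1 and 4 for S phase, 13 and 0 for cholesterol synthesis, 6 and 0 for chaperones, 9 and 1 for chemokine and adhesion genes, 0 and 4 for glycolysis, 13 and 7 for germinal centre identity, 5 and 1 for T and NK markers and 3 and 0 for myeloid markers. Of these lists none kept its call with an estimated correlation (adjusted p of 0.57 or above). Chaperones, chemokine and adhesion genes, glycolysis, ribosomal proteins, germinal centre identity and T and NK markers were not called in the fit of all libraries (adjusted p from 0.077 to 0.64), and the other lists of this paragraph had an adjusted p of 0.15 or above there with an estimated correlation. MS4A1, CXCR5, TRAC, CD68 and MYC were not called in it either. Not called as sets were plasma cells (5 higher, 1 lower), immediate early genes (5 and 2), immunoglobulin genes (4 and 1), MYC targets (0 and 2, with MYC at -0.47), p53 response (3 and 2), apoptosis regulators (4 and 1) and histones (0 and 0).

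**Figure D3:**
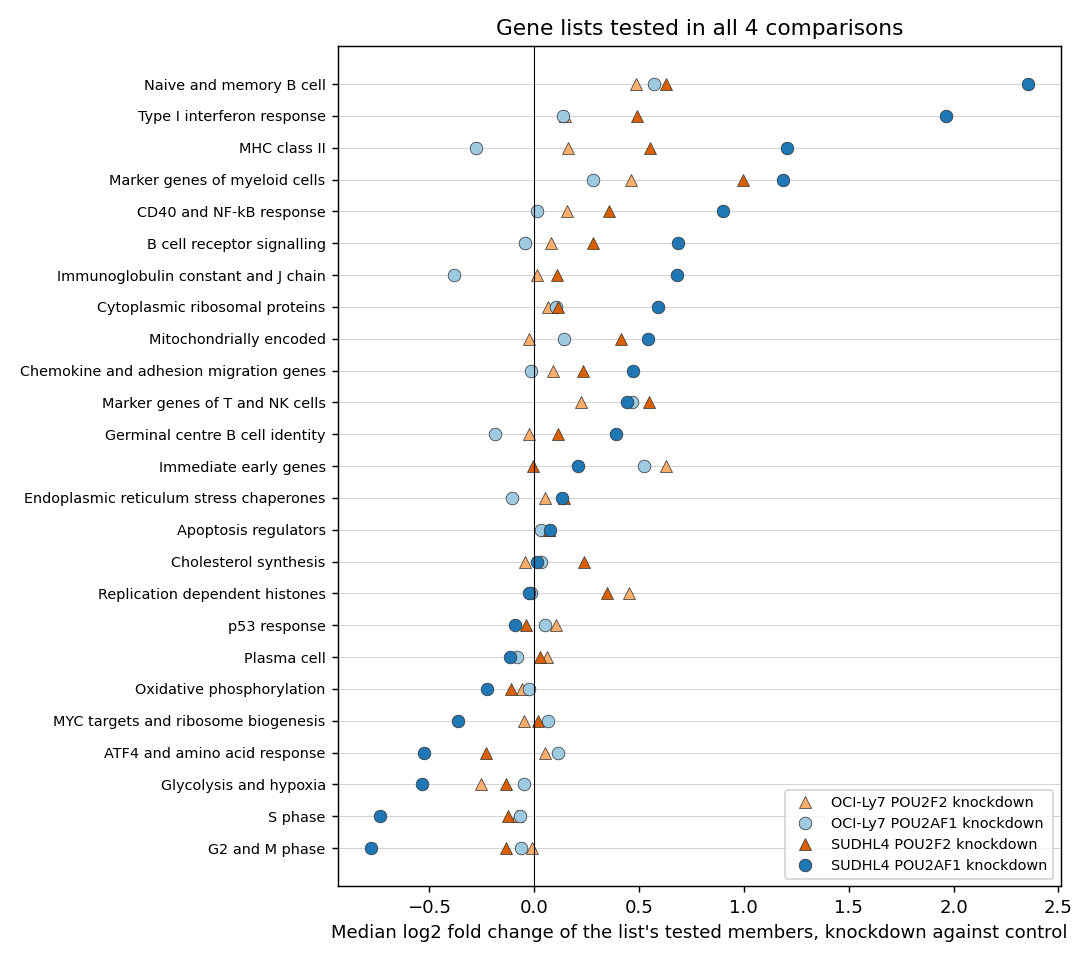
Median fitted log2 fold change of the members of 25 gene lists (horizontal axis) in the 4 knockdown against control comparisons. In SUDHL4 interferon, MHC class II and naive and memory genes are higher and both cell cycle lists lower after POU2AF1 knockdown, and the medians of these 5 lists lie nearer to 0 after POU2F2 knockdown.

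The knockdowns were compared directly within each line. In OCI-Ly7, IRF8 (0.98), RGS13 (0.94), IL4R (1.06), VPREB3 (1.07), IGHM (0.86), GNB3 (2.08), WNT5A (1.57), LOXL2 (1.37) and FCRL3 (1.48) were higher after POU2F2 than after POU2AF1 knockdown, and SCAMP5 (-0.70) was lower. In all 26 genes were called, 22 higher and 4 lower, and within series 201. The series block called 688 with POU2F2 knockdown replicate 3 in batch 1 and 667 without POU2AF1 knockdown replicate 1. With batch as a term the count was 3 without the batch 1 control library, 9 without POU2AF1 knockdown replicate 5, 13 without control replicate 9 or POU2F2 knockdown replicate 4, and 15 without control replicate 8, POU2AF1 knockdown replicate 2 or POU2F2 knockdown replicate 6. Batch 2 alone called 4. The germinal centre list was higher after POU2F2 knockdown, with 3 members higher and 1 lower of 31 and 10 higher and 1 lower adjusted over the list alone (median 0.20, adjusted p = 8.3e-11, and adjusted p = 0.0066 with an estimated correlation; within series 0.13). Both targeted genes are among these 4, and without them the adjusted p with an estimated correlation was 0.0043. Of the 10 lists called, MHC class II (0.40), B cell receptor signalling (0.12) and immunoglobulin genes (0.15) were also higher, but their adjusted p with an estimated correlation was 0.12, 0.083 and 0.14. Only the germinal centre list kept its call with an estimated correlation, and the adjusted p of the 6 further lists was 0.12 to 0.83. Within series glycolysis (adjusted p = 0.27), histones (0.27) and T and NK markers (0.18) lost the call, and plasma cells gained it (0.041, but 0.47 with an estimated correlation), and no list was called there with an estimated correlation (0.13 or above).

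In SUDHL4 the direct comparison called 4443 genes, 2331 higher and 2112 lower after POU2F2 than after POU2AF1 knockdown, and 37 in the fit of all libraries, 7 higher and 30 lower. MYH11 (2.26), RSC1A1 (2.20), CCDC144A (2.20) and ARHGEF28 (1.97) were higher, and FCRL5 (-3.15), C16orf74 (-2.95), MPEG1 (-2.74) and FCGBP (-2.65) were lower. Of these 8 genes only FCRL5 was called in the fit of all libraries (adjusted p = 0.03, the others 0.13 to 0.57). Interferon genes were lower after POU2F2 knockdown in 28 of 32 (median -1.29), MHC class II in 14 of 14 (-0.72), ribosomal proteins in 35 of 40 (-0.49) and naive and memory genes in 14 of 21 (-1.18). G2 and M phase was higher in 50 of 52 (0.63) and S phase in 42 of 43 (0.61). These counts adjusted over the list alone were 30, 14, 40, 15, 51 and 42 in that order. Their camera adjusted p ran from 8.7e-28 to 1.7e-08, but with an estimated correlation was 0.56 or above. In the fit of all libraries it was 0.001 for interferon genes, G2 and M phase and naive and memory genes, 0.012 for S phase, 0.084 for MHC class II and 0.31 for ribosomal proteins.

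The overlap of both knockdowns was large in SUDHL4, and in OCI-Ly7 it depended on the fit. In SUDHL4 765 genes rose and 395 fell in both, against 147 and 81.7 by chance, and 12 went opposite ways. The correlation of fold changes across genes was 0.690, with a range of 0.539 to 0.597 in simulations of unchanged groups that share 1 control. The simulations gave at most 20 shared calls. They let the control vary only by the spread of the SUDHL4 fit, whose only replicates are the POU2F2 knockdown libraries. A control standing further apart could give a higher correlation and more shared calls. With calls from the fit of all libraries 16 genes were shared, out of the 18 called after POU2F2 knockdown, which were 5 without POU2F2 knockdown replicate 1. The control library cannot be split, so the part due to sharing it was not measured. In OCI-Ly7 no gene was shared, since no gene was called after POU2F2 knockdown, and the correlation of 0.459 across genes was that of the simulation (0.460, from 0.407 to 0.508). With the controls split between the knockdowns it was 0.114 and -0.0932. Within series 12 genes were shared, 8 higher and 4 lower, out of the 13 called after POU2F2 knockdown, which were 2 with replicate 3 in batch 1, and the correlation was 0.549 against 0.451 (0.410 to 0.508) in simulations, which shared at most 0 calls. With the controls split within series the correlation was 0.142 and -0.132, with 1 and 0 shared genes, from fewer controls per knockdown. Genes are not independent replicates, so these correlations carry no p.

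Shared genes of the POU2AF1 knockdown in both lines came from separate controls. Of 14895 genes tested in both, 22 rose in both lines against 7.30 by chance (Fisher's exact test, one-sided p = 1.9e-07) and 42 fell in both against 18.4 (p = 1.8e-08), and 24 went opposite ways against 24.5. Fisher's test takes genes as independent, which they are not, so these p do not measure the spread between libraries. The SUDHL4 calls rest on 1 control and 1 POU2AF1 knockdown library. The shared falls with the largest smaller change were POU2AF1, GNB3, LOXL2, MYH11, KCNN3, BCL6, DEPTOR and NUGGC. DEPTOR, an inhibitor of mTOR, fell by 1.10 in OCI-Ly7 and 1.96 in SUDHL4 on the log2 scale. The shared rises were SP140 (1.58 and 3.28), KLHL14 (1.56 and 1.56), AAK1 (1.17 and 2.78), RUFY3 (0.91 and 1.16), OGFRL1 (0.91 and 1.17), STK17A (0.89 and 1.59), TTC39C (0.87 and 1.25) and SP110 (0.81 and 1.33), with OCI-Ly7 given first. MYH11, KCNN3, NUGGC, KLHL14, OGFRL1, TTC39C and SP110 were not called for SUDHL4 in the fit of all libraries (adjusted p from 0.054 to 0.19). Across all genes the correlation between the lines was 0.118. Within series in OCI-Ly7 the shared genes were 193 higher and 172 lower, with 151 opposite against 159 by chance. With SUDHL4 calls from the fit of all libraries they were 7 and 8.

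The POU2F2 knockdown shared no called gene between the lines with batch as a term, since none was called in OCI-Ly7 (edgeR, with 283 at an unadjusted p below 0.05). DESeq2 gave 2 shared genes, and within series 7 of the 13 called genes were shared, 3 higher and 4 lower.

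In some lists that were not called, the median, the mean and the direction of the camera test differed in sign. After POU2AF1 knockdown in OCI-Ly7 these were plasma cells, CD40 and NF-kB, cholesterol synthesis, histones and chemokine and adhesion genes, and after POU2F2 knockdown G2 and M phase. In SUDHL4 they were plasma cells, p53 response and histones after POU2AF1 knockdown, and immediate early genes, MYC targets and p53 response after POU2F2 knockdown. Between the knockdowns they were naive and memory genes, S phase, interferon response and myeloid markers in OCI-Ly7, and plasma cells and epithelial and fibroblast markers in SUDHL4.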

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

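The tests on the depth of the POU2AF1 loss and on the lone control in SUDHL4, the counts of both lines in the fit of all libraries, the 3 tests on POU2F2 knockdown replicate 3, the splits within series and the list tests of line differences were chosen only after the results they concern were seen.

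Fold changes after POU2AF1 knockdown differed between the libraries of the 2 lines, with 1 control and 1 POU2AF1 knockdown library in SUDHL4. The test of the difference called 151 genes, 124 of them higher in SUDHL4 relative to OCI-Ly7. The 5 with the smallest adjusted p were CLCN4, a chloride transporter (log2 difference 3.91), LRRK2 (4.32), NCF1, a subunit of the phagocyte oxidase (2.39), TLR7, a receptor for single-stranded RNA (3.56), and PLEKHO1 (3.76). Among lists the medians of the difference were 1.90 for interferon genes, 1.57 for MHC class II, 1.65 for naive and memory B cells, 0.61 for B cell receptor signalling, 0.63 for germinal centre identity and 0.70 for chemokine and adhesion genes, and -0.71 for G2 and M phase and -0.67 for S phase. With an estimated correlation their adjusted p was 0.0018, 0.023, 0.0018, 0.0018, 0.0094, 0.0094, 0.0064 and 0.037, in that order. The count was 89 without the batch 1 OCI-Ly7 control library and 264 without POU2F2 knockdown replicate 3.

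More genes were called after POU2AF1 knockdown in SUDHL4 (6245) than in OCI-Ly7 (142), and 3 explanations were weighed. A deeper loss of the target is argued against, since 18.3% of the control level was left in SUDHL4 and 6.21% to 19.4% in the 6 OCI-Ly7 libraries. The lone SUDHL4 control as the whole cause is argued against as well, since the difference between the knockdowns, which uses no control, had an SD of 0.364 over genes against 0.151 between the POU2F2 knockdown libraries. A smaller estimated spread in the SUDHL4 fit adds calls, since the fit of all libraries called 315 there, but as the whole cause it is argued against. With 1 spread for both lines the same fit called 154 in OCI-Ly7, and the SD over genes of 1 knockdown against 1 control library was 0.543 in SUDHL4 and 0.247 to 0.488 in OCI-Ly7. This explanation was first left open, because 0.543 exceeds the highest OCI-Ly7 value by less than the SD of those 6 values, and it was judged again with the counts of 315 and 154, by a bound of 1.5 times set after both were seen. A difference between the lines was called for the 151 genes above, but it rests on 1 SUDHL4 library of each kind. It stays open whether the line with its medium, the lone control or that POU2AF1 knockdown library set these genes apart. The same control also enters the SUDHL4 POU2F2 knockdown minus control difference, whose SD over genes was 0.247. A part due to that control is therefore not excluded.

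POU2AF1 knockdown replicate 1 of OCI-Ly7 stood apart, with 25.8% of its reads (95% Wilson interval 25.81% to 25.83%) from mitochondrially encoded genes, and 7.04% to 9.74% in the other 5 libraries. Its mitochondrial share alone as the cause is argued against, because its deviation from the other batch 1 knockdown libraries over nuclear genes had an SD of 0.478, against 0.213 to 0.262 for the others. A bias by transcript length stays open, since its correlation across genes with effective length was -0.135 and those of the others 0.387, 0.112 and -0.272. A stronger response to the knockdown stays open too, at a correlation across genes of 0.148 with the batch 2 knockdown difference, and -0.0469, -0.114 and -0.153 in the others. BCL6 was at 61.0 CPM in this library and at 114 CPM in the nearest other.

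POU2F2 knockdown replicate 3 of OCI-Ly7, a batch 2 library per the labels, had 44214000 reads and 27213 genes with reads, apart from the other 7 libraries of its group. It may have been made with batch 1, since the 5 batch 1 libraries had 26664 to 28726 genes with reads and the 12 other batch 2 libraries 22505 to 23888. An exchanged control is argued against, as its POU2F2 level of 149.99 CPM, though above the 90.4 CPM of the next library of its group, lay below the lowest control at 211 CPM. Its description as 48 h stays open. Its root mean square log2 difference from the POU2AF1 knockdown library so described was 0.39, and those from batch 1 POU2AF1 knockdown libraries not so described were 0.372, 0.392 and 0.510, a margin too small to decide, which was judged so after the values were seen. Its nearest library was the batch 1 control, at 0.163. That control merges files with and without the 48 h description, so its nearness does not separate 48 h from the batch, and a library mixed with control material was not tested.

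The difference between lines of the POU2F2 knockdown was called for 2 genes, the immunoglobulin variable gene IGHV1-69D (log2 difference -2.66) and YBX3, a cold shock domain protein (-2.82). Leaving out single libraries gave 0 to 5. The count fell to 0 in most of these fits and to 1 without the batch 1 control or POU2AF1 knockdown replicate 6, and was 5 without POU2F2 knockdown replicate 1.

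Other single values lay apart from their group by Dixon's test. In all 14 of 102 groups tested held such a value, 5 of them described above, over 31 genes and 3 library measures in OCI-Ly7, and chance flags about 1 in 20 groups. The merged batch 1 control had 52481000 reads and 26795 genes with reads, since it sums repeated files. POU2F2 knockdown replicate 8 had 13.4% mitochondrial reads. POU2F2 knockdown replicate 1 had CHD1 at 19.5 CPM, RUFY3 at 67.6 CPM and FBP1 at 101.9 CPM. POU2AF1 knockdown replicate 6 had KCNN3 at 30.6 CPM. PDZRN4 was at 14.4 CPM in control replicate 9 and MYC at 251 CPM in control replicate 7.

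Other splits of the same OCI-Ly7 libraries were fitted. The 100 splits with batch as a term were drawn without regard to the batch or the series marks. What they exclude therefore holds only if libraries of different batches and series are interchangeable. For the POU2AF1 knockdown 1 of 100 splits with batch as a term, the real one, called as many as 142 genes (highest other 41), which excludes chance only under that limit, and the 20 splits within series are too few (893 genes, highest other 255; 1 split as large). For the POU2F2 knockdown with batch as a term the real count is 0, which all 100 splits reach by definition, so they say nothing about chance, and the highest other, 3504 genes, points to a structure of the samples. Within series only the real split called genes (13, POU2F2 itself among them, highest other 0, 1 of 24 splits), with replicate 3 as labelled. That share is the smallest these splits can give, and the fit was chosen after seeing the data, so they do not exclude chance. POU2F2 knockdown replicates 1 and 3 were never exchanged in them. No splits were fitted with replicate 3 in batch 1, where 2 genes were called. Between the knockdowns 2 of 100 splits with batch as a term were as large as the real 26. That share excludes chance only under the limit above, and the other one called 6192 genes, which again points to a structure and speaks against that limit being met. It put no library of series s0 in its first group, but 3 other splits did the same and called 0 genes, so what sets it apart was not found. The 12 splits within series are too few (201 genes, highest other 0; 1 split as large).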

How the results depend on the processing

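The series blocks, the changed batch of POU2F2 knockdown replicate 3, the separate files, the fits lacking POU2AF1 knockdown replicate 1 within series and the SUDHL4 alternatives in the fit of all libraries with series, without single libraries, or for lists and overlaps were chosen after seeing the data. Of 7398 alternative values of 466 named gene results, 5981 kept direction and side of the threshold, 988 fell below it, 423 rose past it and 6 reversed, none of them called. POU2AF1 after POU2F2 knockdown in OCI-Ly7 was at 0.0069 without the batch 1 control (range without single libraries -0.37 to 0.0069), 0.0052 in batch 2 alone and 0.0058 with the compared groups alone. POU2F2 after POU2AF1 knockdown was at 0.077 without a batch term, and the line difference of POU2AF1 was -0.037 without the batch 1 control (range -0.037 to 0.69). CFLAR after POU2AF1 knockdown was at 0.063 with the replicate block. In the fit of all libraries 271 named values fell below the threshold, 176 kept direction and side of it and 4 rose past it. Leaving out single libraries supplied 2452 of the 5981 that kept both. Where calls moved, the cause was not tested. Depth was not varied. SUDHL4 fits without either POU2F2 knockdown library, or of the control and the POU2AF1 knockdown alone, have no residual degrees of freedom and were not run, and neither was a block in SUDHL4.

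Counts are given in the order POU2F2 and POU2AF1 knockdown in OCI-Ly7, the same in SUDHL4, POU2F2 against POU2AF1 in OCI-Ly7 and SUDHL4, and the line differences of POU2F2 and POU2AF1. The counts reported are 0, 142, 1249, 6245, 26, 4443, 2 and 151. DESeq2 gave 5, 326, 397, 3413, 85, 2224, 29 and 570. Testing against 2-fold with glmTreat gave 5, 77, 607, 1, 134, 0 and 29 from the second on. The fit of all libraries gave 1, 18, 315 and 37 for the POU2F2 knockdown in OCI-Ly7 and the 3 SUDHL4 comparisons, and with series 122, 2734 and 1195 for the latter. Separate files gave 1, 572, 3761, 69, 7155, 30 and 1816, with the POU2AF1 knockdown in SUDHL4 within 1.5 times. The effective length offset gave 1, 452 and 2849 for the POU2F2 knockdown in each line and for POU2F2 against POU2AF1 in SUDHL4. No filter gave 4 for the line difference of POU2F2.

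For the OCI-Ly7 comparisons and line differences, in the order 0, 142, 26, 2 and 151, the series block gave 13, 893, 201, 42 and 1946. With replicate 3 in batch 1 it gave 2, 1122, 688, 52 and 2125, and lacking POU2AF1 knockdown replicate 1 it gave 135, 1693, 667, 130 and 3639. The batch term with replicate 3 in batch 1 gave 1, 267, 120 and 336, the line difference of POU2F2 staying within 1.5 times. No batch term gave 1, 259, 322 and 0, up to the line difference of POU2F2. Batch 2 alone gave 7 and 4 for the POU2AF1 knockdown and between the knockdowns, batch 1 alone 24, and the compared groups alone 3 between the knockdowns. Without the 48 h libraries the POU2F2 knockdown and its line difference each gave 1. In the batch 1 OCI-Ly7 control the files with and without the 48 h description hold nearly the same reads. This alternative therefore cannot separate 48 h material from the rest of that control. Whether replicate numbers pair libraries was not settled. Deviations of same-numbered libraries correlated at -0.83 to 0.83 over 8 pairs (median 0.36), those of the same series at a median of 0.78 over 13 pairs. Pairs that share neither ran from -0.87 to 0.84 over 70 pairs (median -0.34). Same-numbered pairs can also share a series, and the 2 were not separated. The replicate block gave 740 for the POU2AF1 knockdown.

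Leaving out single libraries gave 0 to 1 for the POU2F2 knockdown in OCI-Ly7 (1 without POU2AF1 knockdown replicate 1 or POU2F2 knockdown replicate 3), 8 to 182 for the POU2AF1 knockdown (8 without the batch 1 control), 3 to 33 between the knockdowns (3 without the same control), 0 to 5 and 89 to 264 for the line differences, and for the POU2F2 knockdown in SUDHL4 1388 without the POU2AF1 knockdown library, against 1249. In the fit of all libraries, whose count is 18, it was 5 without POU2F2 knockdown replicate 1 and 14 without replicate 2. In SUDHL4 the comparison of knockdowns gave 4514 without the control.

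Overlaps of 0, 64, 0 and 1160 genes, for the POU2F2 and POU2AF1 knockdowns between lines and for the knockdowns in OCI-Ly7 and SUDHL4, were 2, 3 and 374 with DESeq2 for all but the second. They were 7, 365 and 12 with the series block, 26 and 305 for the second and last at 2-fold, and 15 and 16 with SUDHL4 calls from the fit of all libraries. Called lists numbered 12, 8, 19, 15, 10 and 16, in the order of the first 6 counts. With an estimated correlation and with fry they numbered 1, 3, 0, 0, 1 and 0, and batch 1 alone gave 15 for the POU2AF1 knockdown in OCI-Ly7. With DESeq2 size factors or the length offset, medians changed sign only in lists that were not called.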

Other observations

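All genes below belong to lists fixed beforehand, and which of them to name here was decided after their values were seen. In the germinal centre list of OCI-Ly7 after POU2AF1 knockdown, ELL3, a transcription elongation factor, fell by 0.89 on the log2 scale. In SUDHL4 after the same knockdown LMO2 rose by 2.29 and PAX5, the B lineage factor, by 1.72 on the log2 scale in that line's own fit, and EZH2, a histone methyltransferase, fell by 0.70.

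IRF4, a factor of plasma cell differentiation, fell in SUDHL4 by 1.83 after POU2AF1 knockdown and by 1.82 after POU2F2 knockdown on the log2 scale, and XBP1, a factor of secretory cells, rose by 1.78 and 1.13. Among apoptosis regulators HRK (3.72 and 1.54), CASP10 (3.33 and 1.80) and BCL2A1 (1.13 and 0.75) rose in both knockdowns, and BMF rose after POU2AF1 knockdown (1.71). DUSP6, a phosphatase of ERK, rose by 4.63 and 1.83. The light chain genes IGLC2 (1.21 and 0.82) and IGLC3 (1.42 and 0.91) rose as well. All are log2 changes of the SUDHL4 fit, with 1 control library for both knockdowns. Of the SUDHL4 values given here only PAX5 (adjusted p = 0.0069) and DUSP6 (0.02), both after POU2AF1 knockdown, were called in the fit of all libraries, and the others had an adjusted p from 0.055 to 1.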
